A study of Sus scrofa with 6 samples.

How the data were processed

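RNA sequencing was done on longissimus dorsi muscle in 3 libraries labelled Wei and 3 labelled Yorkshire. Per the labels' protocols, total RNA was extracted with TRIZOL, its integrity was checked on a Bioanalyzer, and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name CASAVA 1.7, TopHat2 2.0.9, edgeR and the genome build Sscrofa10.2, with no role or order. The read counter and the annotation release are not given in the sources used here, nor is whether counting used strand. Reads of overlapping or near-identical genes cannot be told apart on this basis.

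The authors deposited 1 table of 25322 Ensembl pig genes with a raw count and an FPKM value per library, per the file headers. The deposited FPKM values were used only to check the table: over 4854 genes with more than 200 counts in every library, each FPKM was the count divided by a constant per gene and a constant per library. All tests used the deposited counts. Of the gene IDs, 9160 had no symbol in the table, and 1774 of these were given one by ID from a table of gene names. Coordinates are those of the table, in Sscrofa10.2, and count from 1. IGF2, ADIPOQ, FABP4 and MYH4 were not analysed here.

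Libraries were grouped by the breed label. Total counts ranged from 15285197 to 27096747. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 26.3 over genes), so none was taken for a second copy of another. This does not show that the libraries came from separate animals. Intervals and floors cover counting error only, and a count of 0 was read as allowing 3 counts.

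Genes were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, breed only) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are Wei over Yorkshire. The SE is the absolute log2 fold change, fitted without a prior count, over the square root of the F statistic. The biological coefficient of variation was 21.8%. CPM values are after TMM scaling. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the 24 lists with at least 5 tested genes out of 27. Only 8 lists passed at the preset correlation and 0 with an estimated one. GO and KEGG terms of the deposited table with 10 to 500 genes were tested among 11981 annotated genes that passed the filter. Figures were drawn with matplotlib 3.10.9.

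The samples, tests, lists, alternatives and rule for named genes were fixed before the data were examined. The rule took the 12 largest log2 fold changes in each direction among genes with a symbol in the table, an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between breeds. It also took up to 4 called members of each list by adjusted p, or else up to 2 with the highest expression, and a fixed set of muscle and pork genes. Genes named outside it are said to be so, and some genes that the rule took are not reported here. Lists of glucocorticoid-responsive, cell cycle, sterol synthesis and mast cell genes were written after the main results were seen.

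The procedure was tested on simulated counts for the 13209 genes of the Wei against Yorkshire comparison, with 200 genes changed. Each gene was simulated independently with the same common dispersion, 0.0476, so genes that vary more and correlated genes are not covered. It recovered 46.5% of genes changed 2-fold and 96.9% of those changed 4-fold, all with the right sign, and 6% of calls were false. Alternatives in scaling and filter were edgeR's RLE size factors, library size alone, no count filter and a filter of 1 CPM. The other alternatives were the test of DESeq2 1.42.0, limma voom, the replicate number as a block, other thresholds, and leaving out each library. Leaving out mitochondrial genes and ACTA1, and using only the table's own symbols for the lists, were added after the data were seen.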

Results

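Gene expression was measured by RNA sequencing in the longissimus dorsi, the long back muscle sold as pork loin, of 2 pig breeds, Wei and Yorkshire. There were 3 libraries per breed. The Wei pigs were slaughtered at 90 kg, and the labels say that the Yorkshire pigs were kept in a similar way. No slaughter weight is given for the Yorkshire pigs. Total gene counts were 27096747, 17876646 and 25676693 in Yorkshire replicates 1 to 3 and 15285197, 15798244 and 22570075 in Wei replicates 1 to 3. Mitochondrial genes took between 5.38% and 10.18% of the counts of a library. ACTA1, the skeletal muscle actin gene, took between 3.77% (Wei replicate 1) and 8.76% (Yorkshire replicate 1). The groups follow the breed label. The titles and column names of the libraries labelled Yorkshire start with LWH and those of the libraries labelled Wei with YH, codes that the labels do not explain. If the breed labels were exchanged, each direction given here would turn. The labels do not give the sex or age of the animals. Genes of the Y chromosome had 6901 counts in Wei replicate 2 and at most 14 in each of the other libraries. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

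The comparison asked which genes differ in loin muscle between Wei and Yorkshire pigs. UCP3, a mitochondrial carrier that rises when muscle burns fatty acids, and ACSL1, which activates fatty acids, were higher in Wei muscle. FBXO32, a ubiquitin ligase of muscle protein breakdown, and ESRRG, a nuclear receptor of oxidative metabolism, were also higher in Wei. KIT, a receptor tyrosine kinase of pigment and mast cells, and the basement membrane collagens COL4A1 and COL4A2 were lower in Wei. Of 13209 genes tested with edgeR's quasi-likelihood test, 671 passed a Benjamini-Hochberg adjusted p of 0.05, with 361 higher and 310 lower in Wei. Over all tested genes, the 3 Wei and 3 Yorkshire values did not overlap for 29.6%, where chance gives 10%. The first principal component carried 44.8% of the variance and separated the breeds, and the second carried 17.3%. The count of calls was sensitive to single libraries: it was 276, 60 and 165 without Yorkshire replicates 1, 2 and 3, and 216, 394 and 240 without Wei replicates 1, 2 and 3.

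Among genes higher in Wei, UCP3 (ENSSSCG00000014834, chromosome 9, 9166711 to 9179299 in Sscrofa10.2) had the smallest p. It stood at 203 ± 31.7 CPM (SD, n = 3) in Wei and 14.7 ± 3.46 in Yorkshire, a log2 fold change of 3.79 ± 0.22 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00091). HOOK1, a linker of cargo to microtubule motors (chromosome 6, 140117181 to 140190970), had a log2 fold change of 5.42 ± 0.48, from 8 counts in all Yorkshire libraries to 269 in Wei. ESRRG (chromosome 10, 8644061 to 8823152) rose by 3.54 ± 0.32 on the log2 scale, to 20 ± 4.86 CPM in Wei from 1.71 ± 0.73 in Yorkshire. FBXO32 (chromosome 4, 16638622 to 16669461) stood at 227 ± 133 CPM in Wei against 27.9 ± 7.07 in Yorkshire, a log2 fold change of 3.02 ± 0.41. Within the rule for named genes, which needs a symbol in the deposited table and a minimum expression, the next largest increases were those of NPAS2 (2.95), NMNAT2 (2.91), KLF11 (2.87), HOXD1 (2.84), ASPA (2.74), GALNT15 (2.59) and AMPD3 (2.49) on the log2 scale. TMP-SLA-5, a histocompatibility gene, had a log2 fold change of 3.56 ± 0.78. Its family has near-identical members, so its reads could be split between them and the value is uncertain.

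**Figure D1:**
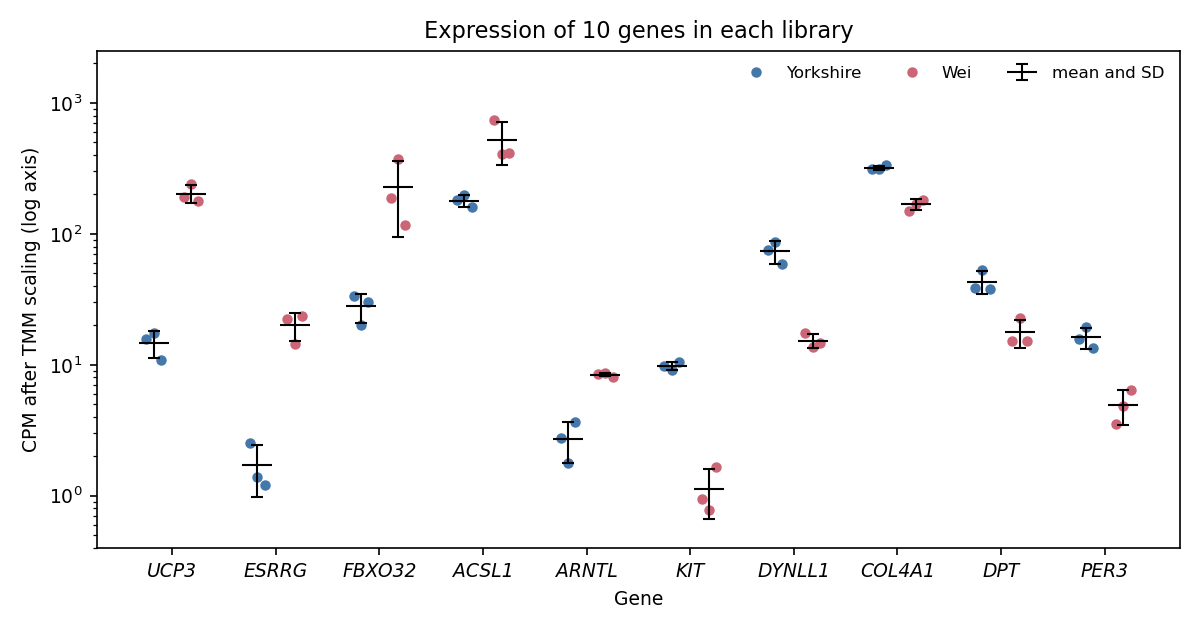
Expression of 10 genes in CPM (log axis) after TMM scaling, by breed; points are libraries, and bars give the mean and SD of 3 libraries. The Wei libraries lie above all Yorkshire libraries for UCP3, ESRRG, FBXO32, ACSL1 and ARNTL and below them for KIT, DYNLL1, COL4A1, DPT and PER3.

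Among genes lower in Wei, KIT (ENSSSCG00000008842, chromosome 8, 43550236 to 43602062) stood at 1.13 ± 0.47 CPM in Wei and 9.79 ± 0.62 in Yorkshire, a log2 fold change of -3.08 ± 0.28 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00353). DYNLL1, a dynein light chain, had a log2 fold change of -2.27 ± 0.18, and RALGPS2, an exchange factor for Ral GTPases, one of -3.40 ± 0.39. ANKRD1, a stretch-responsive muscle ankyrin repeat gene, had one of -3.06 ± 0.57, with 1037 CPM in Yorkshire replicate 1 and 329 and 321 in the other Yorkshire libraries. Within the same rule the next largest decreases included those of ADAMTS20 (-2.78), ART4 (-2.48), EXTL1 (-2.47), RCOR2 (-2.47), MKI67 (-2.36), C1QTNF6 (-2.29) and SPP1 (-2.25). Of the genes named by size of change, UCP3, ESRRG, HOOK1, KIT, RALGPS2 and DYNLL1 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with every library left out in turn. The remaining ones named here missed it in at least 1 such fit.

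In the fatty acid uptake and oxidation list, 7 of 29 tested genes were higher in Wei and none was lower. Adjusted over the list alone, 14 were higher and 0 lower. Besides UCP3, these included ACSL1 at 1.55 ± 0.24 (log2, SE), ECI1 at 0.997 ± 0.169 and ACADS at 0.65 ± 0.13, the last 2 being enzymes of fatty acid breakdown. The median log2 fold change of the list was 0.57. The citric acid cycle and respiratory chain list had 5 of 53 genes higher and none lower, and 12 higher and 1 lower adjusted over the list alone. OGDH (0.76 ± 0.12) and SDHA (0.74 ± 0.16), enzymes of the citric acid cycle, were among them. With limma's camera and a preset correlation the adjusted p was 4.03e-06 for both lists, and with an estimated correlation it was 0.687 for the fatty acid list and 0.749 for the respiratory list. The fatty acid list had 3, 1 and 1 calls without Yorkshire replicates 1, 2 and 3 and 3, 7 and 3 without Wei replicates 1, 2 and 3, and the respiratory list had 0, 0 and 0, and 1, 2 and 1. Among genes higher in Wei, the KEGG term Fatty acid degradation (4 genes, Fisher's exact test, adjusted p = 0.412) and the GO term fatty acid metabolic process (10 genes, adjusted p = 0.409) did not pass.

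Slow and fast contractile genes showed no call in either direction, over all genes or adjusted over the list alone: 0 of 12 slow fibre genes and 0 of 11 fast fibre genes passed edgeR's test. DESeq2 and limma voom called 0 in both lists as well. Without Wei replicate 2, 2 slow fibre genes were higher and the slow median was 0.50; with any other library left out no slow or fast gene passed. In the slow list 4 members had an unadjusted p under 0.05, against 0 in the fast list, and 11 of 12 had a positive change, with a median of 0.30. MYH7, the slow myosin heavy chain, had a log2 fold change of 0.48 ± 0.24 and MYBPC1 one of -0.51 ± 0.18. MYH2 had one of -0.47 ± 0.21 and the gene listed as MYH1 one of 0.062 ± 0.329, and the near-identical myosin genes make these values uncertain. The glycolysis and glycogen list had 3 of 24 genes higher, HK2 (1.17 ± 0.18), PHKB (0.71 ± 0.15) and UGP2 (0.77 ± 0.17), and 3 higher and 1 lower adjusted over the list alone. Of its genes 1, 0 and 0 were higher without Yorkshire replicates 1, 2 and 3, and 1, 2 and 1 without Wei replicates 1, 2 and 3, with 1 lower without Wei replicate 2.

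In the extracellular matrix list 7 of 30 genes fell in Wei and none rose, and adjusted over the list alone 16 fell and 1 rose. COL4A1 (chromosome 11, 84373663 to 84432619) stood at 168 ± 16.5 CPM in Wei and 320 ± 11.7 in Yorkshire. Its log2 fold change was -0.93 ± 0.13, against -1.01 ± 0.14 for COL4A2, -1.15 ± 0.22 for BGN, a small proteoglycan, and -1.03 ± 0.21 for COL15A1. The list median was -0.64, with a camera adjusted p of 3.18e-06 at the preset correlation and 0.749 with an estimated correlation. In the fibroblast list 1 of 14 genes passed, DPT, at -1.29 ± 0.21, and 12 of 14 had a negative change. The same gene alone passed adjusted over the list alone, and the camera adjusted p was 0.0444, or 0.749 with an estimated correlation. The matrix list had 3, 0 and 2 calls without Yorkshire replicates 1, 2 and 3, and 3 without any 1 of the Wei replicates. DPT missed the threshold without Yorkshire replicate 2, Wei replicate 1 or Wei replicate 3.

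Clock genes moved in both directions. Of 18 tested, 3 were higher in Wei, ARNTL at 1.61 ± 0.26, NPAS2 at 2.95 ± 0.53 and BHLHE41 at 1.55 ± 0.33, and 2 were lower, PER3 at -1.71 ± 0.24 and PER2 at -1.82 ± 0.37. Adjusted over the list alone, 9 were higher and 3 lower. ARNTL and NPAS2 encode activators of the circadian clock, PER2 and PER3 repressors, and BHLHE41 another repressor. BHLHE41 was named after its values were seen. The camera adjusted p was 0.0859 at the preset correlation. Calls higher and lower numbered 4 and 1, 0 and 0, and 2 and 1 without Yorkshire replicates 1, 2 and 3, and 2 and 1, 3 and 2, and 1 and 2 without Wei replicates 1, 2 and 3.

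In the muscle protein breakdown list FBXO32 and SQSTM1, an autophagy receptor (1.51 ± 0.21), were higher and CAPN2, a calpain, was lower (-0.70 ± 0.16), of 18 tested; the counts were the same adjusted over the list alone. The camera adjusted p was 0.018 and 0.687 with an estimated correlation. In the lipid synthesis list LPIN1 was higher (1.53 ± 0.19) and FADS1, a fatty acid desaturase, lower (-1.76 ± 0.22), of 18, with 2 higher and 1 lower adjusted over the list alone. FASN (-0.63 ± 0.34) and SCD (-1.62 ± 0.81) missed the threshold. In the growth factor and insulin list IGF1R (0.90 ± 0.14) and GHR (0.57 ± 0.12) were higher, of 22, with 3 higher and 4 lower adjusted over the list alone. GHR and LEPR (2.53 ± 0.57) were the 2 genes higher among 17 pork quality candidates, with 3 higher and 2 lower adjusted over the list alone. MEF2A was the 1 gene higher among 12 myogenic genes (0.84 ± 0.14), with 3 higher and 1 lower adjusted over the list alone. CHRNG, the fetal acetylcholine receptor subunit, was the 1 gene lower among 7 developmental contractile genes, with 4 counts in all Wei libraries and 137 in Yorkshire. Adjusted over the list alone 2 were lower, and the camera adjusted p was 0.0444, or 0.687 with an estimated correlation. Of the called genes in these lists that are named here, FADS1 passed with every library left out in turn, and each of the others missed in at least 1 such fit. MSTN (-1.33 ± 0.40), PRKAG3 (-0.80 ± 0.20) and IGF1 (-0.82 ± 0.39), genes of muscle growth and glycogen, had edgeR quasi-likelihood adjusted p of 0.0921, 0.0577 and 0.254 after Benjamini-Hochberg adjustment.

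Yorkshire replicate 3 stood apart in the lymphocyte and macrophage lists. The mean log2 CPM of the lymphocyte list was 1.92 in Yorkshire replicate 3, 0.32 and 0.38 in the other Yorkshire libraries and between -0.23 and 0.0098 in Wei. The macrophage list stood at 3.07 in Yorkshire replicate 3 and between 1.29 and 1.67 in the other 5. No gene of the lymphocyte (11 tested), macrophage (13), interferon (28) or antigen presentation (16) lists passed edgeR's test over all genes. At an unadjusted p under 0.05 there were 8, 1, 6 and 2. DESeq2 called 3, 1, 2 and 0, all lower in Wei, and limma voom 0 in each. Adjusted over the list alone, 8 lymphocyte genes were lower in Wei and none of the other 3 lists had a call. The camera adjusted p at the preset correlation was 0.00801 for the lymphocyte list and 0.00677 for the interferon list, and 0.749 for both with an estimated correlation. The median change of the lymphocyte list was -1.49, and -0.60 without Yorkshire replicate 3. That of the interferon list was -0.63, -0.27 without Yorkshire replicate 3 and -0.36 without Wei replicate 2, the library with its lowest mean log2 CPM (1.27, against at least 2.04 in the others).

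Of the remaining lists, PLIN4 was the 1 gene higher of 7 adipocyte markers (0.70 ± 0.14), and DUSP1 the 1 gene higher of 24 immediate early genes (1.53 ± 0.31), with the same counts adjusted over the list alone. Both missed the threshold without Yorkshire replicate 2, Yorkshire replicate 3 or Wei replicate 1, PLIN4 also without Wei replicate 3 and DUSP1 also without Wei replicate 2. No gene passed among 13 endothelial, 9 smooth muscle and pericyte, 6 Schwann cell and 21 heat shock genes with edgeR. At an unadjusted p under 0.05 there were 1, 5, 1 and 5. DESeq2 called 0, 1, 0 and 3, all higher in Wei, and limma voom 0 in each. Adjusted over the list alone, 1 smooth muscle gene was higher and 1 lower, with none in the other 3. Of red blood cell markers 3 were tested, and 0 passed with edgeR, DESeq2 or limma voom or at an unadjusted p under 0.05. Neutrophil and Y-linked markers had 0 genes above the count filter.

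**Figure D2:**
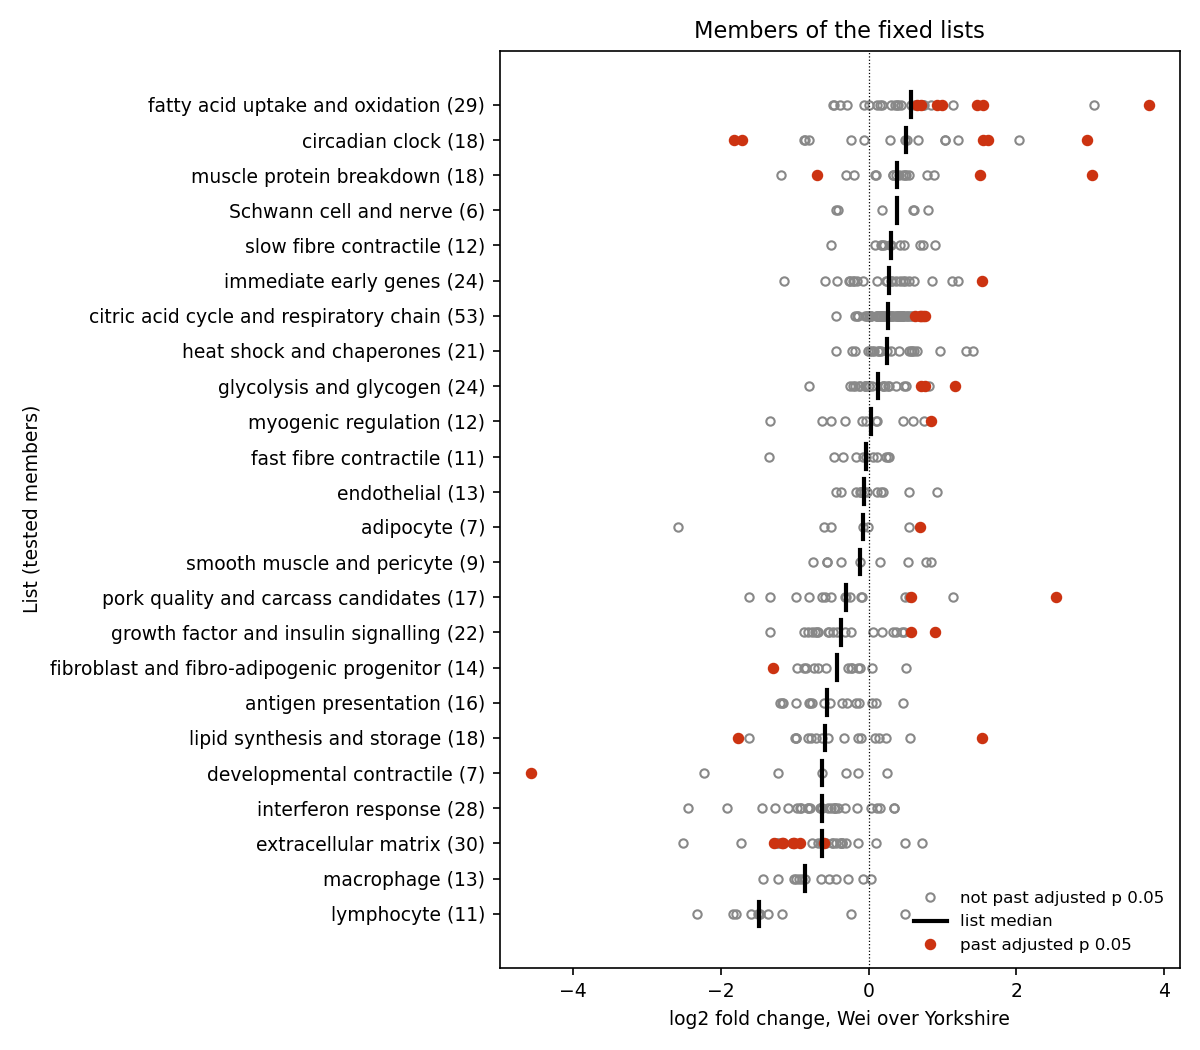
Log2 fold change, Wei over Yorkshire, of each tested gene of the 24 lists with at least 5 tested genes; filled points passed an adjusted p of 0.05 in edgeR's test over all genes, open points did not, and bars are list medians. The fatty acid list has the highest median, 0.57, and the lymphocyte list the lowest, -1.49, with no filled point.

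Annotation terms were tested among the called genes with a one-sided Fisher's exact test and Benjamini-Hochberg adjustment. Genes lower in Wei were enriched for ribosomal, matrix and sterol terms. The KEGG term Ribosome held 15 of the 294 annotated genes that were lower (adjusted p = 8.96e-05), the GO term extracellular matrix 18 (adjusted p = 0.00152) and the KEGG term Steroid biosynthesis 5 (adjusted p = 0.0109). Genes higher in Wei were enriched for ubiquitin ligase complex, with 21 of 332 annotated genes (adjusted p = 0.000113), and protein ubiquitination, with 30 (adjusted p = 0.00104). In all, 8 GO terms were enriched among genes higher in Wei, and 11 GO and 2 KEGG terms among genes lower. Without Yorkshire replicates 1, 2 and 3 the number of enriched terms was 5, 0 and 0, and without Wei replicates 1, 2 and 3 it was 10, 6 and 10.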

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

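Genes of the Y chromosome, which no comparison uses, had 6901 counts in Wei replicate 2. The highest sum in a Yorkshire library was 10, and Wei replicates 1 and 3 had 9 and 14. DDX3Y had 2892 of these counts and USP9Y 1487, and SRY had 0 in each library. The labels give no sex, but these counts point to a male source for Wei replicate 2. No other library of either breed showed this, so the Wei group was mixed in it and the Yorkshire group was not. Without Wei replicate 2, edgeR's quasi-likelihood test called 394 genes in place of 671, with 259 higher and 135 lower in Wei. UCP3, KIT and ESRRG passed the threshold without it. No called gene changed direction, but the values of the called genes do not overlap between the breeds, so leaving out a library could hardly turn one.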

How the results depend on the processing

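The alternatives were planned except those without mitochondrial genes and ACTA1 and with the table's own symbols only, and the test over other splits was written down after its result was seen. None of the 671 calls changed direction under any alternative in which the gene was tested. This is no test of them: the Wei and Yorkshire values of all 671 do not overlap. Leaving out a library could therefore hardly turn a direction, and the other scalings moved the median of all genes by at most 0.021. RLE scaling, library size alone, no filter, the 1 CPM filter, limma voom and the fit without mitochondrial genes and ACTA1 gave between 466 and 814 calls. DESeq2 called 1273 genes, 715 higher and 558 lower, and 98 terms; the cause was not tested. A log2 fold change of at least 1 left 378 genes (193 higher, 185 lower), and an adjusted p under 0.01 left 52 (33 and 19), since both thresholds are stricter. Leaving out 1 library left 60 to 394 genes, 37 to 259 higher and 23 to 135 lower, 5 to 13 lists and 0 to 10 terms, with fewer samples in each fit. Without Yorkshire replicate 2 the total was the lowest. Camera called 8 lists at the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.687. Of 67 named genes past the threshold, 49 passed it under each alternative that kept all libraries, and 13 without each library in turn. The replicate block gave 477 genes (258 higher, 219 lower), 11 lists and 19 terms. Deviations of same-numbered libraries correlated at 0.14, -0.0066 and 0.022 across genes, so the numbers were not taken as pairs. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, gave as many as 671 genes, and 1, again the real one, as many as 21 terms; the highest other split gave 0 of each. For lists called by camera, 9 of the 10 splits gave at least the real 8, and the highest other gave 12. Alternatives for normalized values were not run, since counts were used. At the depth and number of these libraries, with the same common dispersion for all genes, 46.5% of simulated 2-fold changes were recovered. The real genes differ in spread, so this share need not hold for them. Whether depth, spread or the number of libraries sets this limit was not tested.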

Other observations

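All gene groups in this paragraph were singled out after their values were seen. A cell cycle list was prompted by MKI67, a proliferation marker, and is given without it. Of its other 17 tested genes, 4 were lower in Wei and 0 higher, with a median log2 fold change of -1.51. TOP2A, which untangles replicating DNA, was at -2.02 ± 0.42. Of the 17 genes, 12 were highest in Yorkshire replicate 3, the library with the highest lymphocyte and macrophage scores. ASPM, the called gene with the largest change (-5.64 ± 0.58), was not: it stood at 3.83, 2.38 and 3.21 CPM in Yorkshire replicates 1 to 3. It had 3 counts in all Wei libraries and 229 in Yorkshire, and passed with every library left out in turn. In the same order, the other called genes stood at 0.59, 0.66 and 0.69 (CDC20), 1.09, 1.22 and 1.46 (KIF20A) and 2.81, 5.31 and 7.36 CPM (TOP2A). Without Yorkshire replicate 3, 1 of 13 tested genes was lower, with a median of -0.93. Limma's camera gave p = 6.39e-08 at the preset correlation and 0.0672 with an estimated correlation. Of 16 sterol synthesis genes 3 were lower and 0 higher in Wei by edgeR's test: CYP51A1 (-1.49 ± 0.24), SQLE (-2.16 ± 0.37) and MSMO1 (-0.99 ± 0.21). The median was -0.46. TOP2A and each of these 3 sterol genes missed the threshold in at least 1 fit with a library left out. All 60 tested cytosolic ribosomal protein genes had a negative change, with a median of -0.41, and 9 passed the threshold, among them RPL9 (-0.72 ± 0.16) and RPS4X (-0.59 ± 0.12). RLE scaling, library size alone and leaving out mitochondrial genes and ACTA1 moved the median of all genes by at most 0.021, too little to test scaling as the source. The ribosomal median was negative under each of these, and the calls, 9 in the main fit, numbered 8, 1 and 11. They numbered 1, 0 and 0 without Yorkshire replicates 1, 2 and 3, and 0, 0 and 1 without Wei replicates 1, 2 and 3.

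Among 20 tested HOX genes, 6 were higher and 1 lower in Wei, also singled out after the values were seen. HOXD9 was at 1.30 ± 0.17, HOXA7 at 1.93 ± 0.27 and HOXA4, the 1 lower gene, at -1.73 ± 0.26. HOXD9 and HOXA7 passed the threshold with every library left out in turn, and HOXA4 missed it in at least 1 such fit. An unnamed gene (ENSSSCG00000026009, chromosome 5, 65984979 to 66021167) had 0 counts in each Yorkshire library and 65, 129 and 156 in Wei, at least 154-fold higher against a floor of 3 counts over the Yorkshire group. A gene model named NRK (ENSSSCG00000030817, chromosome X, 100896653 to 100965138) had 0 counts in each Wei library and 17, 13 and 21 in Yorkshire, at least 12.9-fold lower in Wei against the same floor. It missed the threshold without Yorkshire replicate 2. It overlaps another model of that name (chromosome X, 100950999 to 101018633), so its value is uncertain. That other model had 20 counts in all Wei libraries and 226 in Yorkshire, a log2 fold change of -3.05 ± 0.33, so NRK was not absent in Wei. In Yorkshire replicate 1, ND4L took 0.0622% of counts, against at most 0.00597% in the other libraries. This was not particular to ND4L: ATP8 took 0.0358% there against at most 0.00653%, ND1 0.499% against 0.155% and ND2 0.589% against 0.185%. The mitochondrial genes COX1, ATP6, COX3, ND4 and CYTB were not highest in that library.

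The tests in the next 3 paragraphs were chosen after the results were seen. In the fatty acid oxidation list 7 of 29 genes were higher in Wei, and the list's call was lost with an estimated correlation (adjusted p = 0.687). RLE scaling, library size alone and leaving out mitochondrial genes and ACTA1 moved the median of all genes by at most 0.021, too little to test scaling or a few abundant genes as the source, so both stay open. More slow fibres in the Wei samples cannot be told apart from this, because the slow fibre list differed by 0.26 ± 0.31 (mean log2 CPM, Wei minus Yorkshire, SE) and the fatty acid list by 0.67 ± 0.14. Longer feed withdrawal before slaughter is a candidate explanation: sterol synthesis genes, which fall in fasting, were lower as a set in a list written after the main results were seen and tested without the member that prompted it (camera p = 0.0394 with an estimated correlation). A stronger glucocorticoid response stays open, with limma's camera p = 0.352 with an estimated correlation and a median of 0.58 over the tested genes. Breed itself, age, slaughter weight and fasting time were not separated by this design.

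Clock genes differed between the breeds. Adjusted over the list alone, 9 were higher and 3 lower in Wei, which argues against scaling as the whole source, since scaling moves all genes of a library the same way. The 5 genes that peak with ARNTL were higher by 1.21 ± 0.17 to 1.46 ± 0.17 (mean log2 CPM, SE) without each library in turn. The size of this mean thus did not rest on a single library. All 5 had a positive change with all libraries, so leaving out 1 library could hardly turn the sign and was no test of it. For the other clock genes no such mean was tested. Without Yorkshire replicate 2 no clock gene was called, but calls over all genes also fell, from 671 to 60. The median log2 fold change of the clock list was then 0.52, against 0.51 with all libraries. A different time of day at slaughter could give such changes, and was tested with all clock genes of known phase. With all libraries, the 5 that peak with ARNTL were higher by 1.33 ± 0.18, but the 10 that peak against it differed by 0.064 ± 0.264 and went both ways, with PER2 and PER3 lower and NR1D1 at 2.04 ± 0.51, so the 2 groups did not simply oppose each other. Time of day cannot be told apart from breed here, since the labels give no hour.

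KIT was lower in Wei, at -3.08 ± 0.28. Fewer mast cells in the Wei samples are argued against by MS4A2, a mast cell marker, at 0.40 ± 0.44, although only 2 of 11 mast cell genes passed the count filter (GATA2 was at 0.53). If RNA followed copy number in proportion, 3 times as many copies in Yorkshire, an assumed limit, would alone give about -1.6. The measured -3.08 lies below that by more than 2 SE. Copy number was not measured, so this cannot decide whether the number of copies differed. PDGFRA, the gene listed next to KIT, was at -0.73 ± 0.34, which argues against a fall as large as that of KIT at PDGFRA. A smaller fall over the neighbouring genes stays open, and no other neighbour was tested. What lowered KIT stays open. A sequence variant that lowers alignment of Wei reads was not tested.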
